A study of Mus musculus with 6 samples.

How the data were processed

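Total RNA from mouse brain was profiled on 6 one-colour Affymetrix oligonucleotide arrays, 3 from mice lacking Dap12 (the protein encoded by Tyrobp) and 3 from heterozygous mice, all at 1 month of age. Per the labels' protocols, RNA was extracted with Trizol followed by RNeasy columns, converted to biotin-labelled cRNA by the Affymetrix one-cycle method and hybridised. Per the submitters' processing notes the signals came from GCOS, the Affymetrix scanner software; its version, the summary algorithm, the detection calls and the scale factors were not given in the sources used here. The deposited value of each probe set (a set of short probes for 1 transcript) is a linear signal intensity above 0. The trimmed mean of the deposited intensities, with 2% removed at each end, was 100 on every array, so each array had been scaled as a whole, and that scaling was kept.

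The table holds 45101 probe sets, 64 of them controls. By the platform annotation, 34945 probe sets had 1 gene symbol, 932 had several and 9160 had none; genes were named only from probe sets with 1 symbol, of which 1 was updated through its gene identifier. Neighbourhood on chromosome 7 was taken from RefSeq genes of the mouse assembly GRCm38.p6, which placed 34881 probe sets; no coordinates are printed because no assembly is named for the arrays. Hbb-bs and Ddx3y, which the rule for named genes lists, were not analysed here.

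Signals were transformed as log2(signal + 16). Fold changes below are on this scale and understate the change of dim probe sets. Control probe sets were left out and the probe sets whose mean over the 6 arrays lay above the median were tested, 22518 in all, of which 19922 had 1 symbol. Differences (knockout minus heterozygous) were estimated with limma 3.58.1 in R 4.3.3 (lmFit with 1 term for group, eBayes with a trend of the spread on level, two-sided) and adjusted by Benjamini-Hochberg, with a threshold of 0.05. Errors of log2 changes are standard errors from this model, and errors of signals are SD with n = 3. Exact permutation tests were two-sided; with 3 arrays against 3 their smallest possible p is 0.1. The number of arrays limits the precision throughout.

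Gene lists were tested with camera in limma, with a preset correlation of 0.01 between genes, on 1 probe set per gene (the one with the highest mean over the 6 arrays), over 11467 genes and the 27 lists with at least 5 genes tested. In 2 further versions, camera with a correlation estimated per list and fry, the same values were used. The shift of a list is the median log2 change of its members minus the median of all genes tested, and its adjusted p compares it with the other genes. The lists covered microglia; Tyrobp receptors and signalling; genes flanking Tyrobp; myelin and mature oligodendrocyte; oligodendrocyte precursor; astrocyte; general neuron; synaptic vesicle and release; glutamate and GABA receptors with BDNF signalling; striatal medium spiny neuron; thalamus; hypothalamus; midbrain dopamine and serotonin neuron; cortex and hippocampus; choroid plexus; ependyma; pituitary; cerebellum and hindbrain; endothelium and pericyte; meninges and fibroblast; blood cells; interferon response; complement and antigen presentation; inflammation and disease-associated microglia; immediate early genes; heat shock and stress; cholesterol synthesis; oxidative phosphorylation; cytosolic ribosomal proteins; and sex. Pituitary and blood cells had 1 gene tested each, and the sex list is given as values. Some genes stand in more than 1 list, such as Csf1r, Itgam and Siglech in both the microglia and the Tyrobp receptor lists.

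The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named Tyrobp; the 15 probe sets with the smallest p in each direction, since over 30 passed; the 2 members of each list with the smallest p; a fixed set of microglial, myelin, synaptic and regional genes; and Xist as a check of sex. Genes outside the rule are called members of their list, and were picked as examples after their values were seen. Whether probe sets of genes within 10 Mb of Tyrobp passed an unadjusted p of 0.05 more often than others was tested with Fisher's exact test.

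Alternatives were quantile normalization, centring each array on its median, a floor of 1 in place of the added 16, 64 added, no filter on level, a filter that removed 75% of probe sets, eBayes without trend or with robust estimation, array weights, the Xist level as a covariate, leaving out each array in turn, the mean of all tested probe sets of a gene, omission of genes near Tyrobp, and windows of 5 and 20 Mb. Added after the data were seen were a covariate for regional make-up, the omission of knockout 67 and 68 together and of knockout Ko1 and heterozygous 81 together, a fit on 1 probe set per gene, and lists without probe sets above a mean signal of 2000.

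The procedure was tested on simulated data with the spread of these arrays over 22518 probe sets. For the knockout against heterozygous comparison it recovered 22% of 50 probe sets changed by 1 on the log2 scale, 90% at 2, 98% at 3 and 100% at 4, called 14 unchanged probe sets, and called 0 with no change simulated (limma, adjusted p under 0.05). A microglia list shifted by 0.5 on the log2 scale had an adjusted p of 1.21e-14 with camera, 0.0203 with an estimated correlation and 0.013 with fry, and 0 of the 24 lists without its members were called. Each probe set was simulated independently, without correlation between genes or differences between whole arrays. These results therefore do not measure the rate of false calls on the real arrays, where genes move together. Values were read and plotted with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.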

Results

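Transcript levels were measured in the brains of mice lacking Dap12 and of heterozygous mice. Dap12, encoded by Tyrobp, is an adaptor protein that carries the signal of receptors such as Trem2 in microglia, the resident immune cells of the brain. The design describes the tissue as midbrain together with diencephalon and basal ganglia. There were 3 knockout arrays, from the samples named 67, 68 and Ko1, and 3 heterozygous arrays, from 75, 76 and 81. The labels say no more about the animals than this, so the p-values measure the spread between these samples. Median signals were 40.41, 35.78 and 24.68 on knockout 67, 68 and Ko1 and 20.34, 21.98 and 21.35 on heterozygous 75, 76 and 81, although the trimmed mean was 100 on each. The highest signals were 46271, 28023.6 and 16672.9 on the knockout arrays and between 7417.29 and 7789.79 on the heterozygous arrays. Across probe sets the heterozygous arrays correlated with each other at 0.969 to 0.982, knockout Ko1 correlated with them at 0.943 to 0.954, and knockout 67 and 68 correlated with the other arrays at 0.889 to 0.921.

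Tyrobp was lower on every knockout array than on every heterozygous array. Its probe set gave signals of 2.277, 23.67 and 12.89 on knockout 67, 68 and Ko1 (12.9 ± 10.7, SD, n = 3) and of 70.67, 68.19 and 77.6 on heterozygous 75, 76 and 81 (72.2 ± 4.87, SD, n = 3). It fell by 1.68 ± 0.33 on the log2 scale (limma adjusted p = 0.0439; exact permutation p = 0.1, the smallest possible). Each array thus carried the Tyrobp level its genotype label called for, though where this probe set lies relative to the deleted part of the gene was not examined. The call was lost when any array other than knockout Ko1 was left out, with log2 changes from -1.94 without knockout 68 to -1.38 without knockout 67. It was also lost with a floor of 1 (-3.02, adjusted p = 0.0983), without a filter on level (adjusted p = 0.0952) and without a trend of the spread (adjusted p = 0.0505). The same happened with the Xist level, which was highest on knockout 67, as a covariate (-1.19, adjusted p = 0.192).

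**Figure D1:**
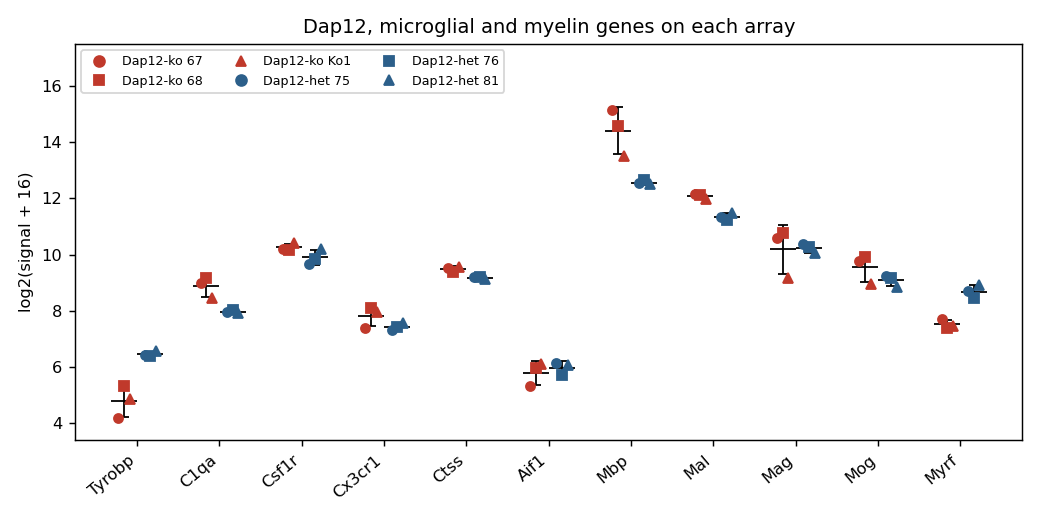
Signals of Tyrobp, 5 microglial genes and 5 myelin genes on each array, on a log2(signal + 16) axis; red points are knockout arrays, blue points heterozygous arrays, and bars show the mean and SD (n = 3). Tyrobp lies at 2.277 to 23.67 in signal on the knockout arrays and at 68.19 to 77.6 on the heterozygous arrays, while Mag overlaps between the groups.

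Beyond the targeted gene, the comparison asked which transcripts differ between brains with no Dap12 and brains with 1 working copy of the gene. The largest increase was in a probe set of Norad, a long non-coding RNA. It rose by 3.83 ± 0.32 on the log2 scale, from a signal of 22.8 ± 10.5 to 546 ± 216 (SD, n = 3; adjusted p = 0.0128). Probe sets also rose for Kif5c, a kinesin motor of axonal transport (2.94 ± 0.31), Gas7 (2.83 ± 0.26) and Dlg4, which encodes the postsynaptic scaffold PSD-95 (2.74 ± 0.31). So did probe sets of Map2, a dendritic microtubule protein (2.73 ± 0.30), Syt1, the calcium sensor of transmitter release (2.61 ± 0.28), and Gabrb2, a GABA-A receptor subunit (2.41 ± 0.27). The others among the 15 increases with the smallest p were in Hnrnpab, Strbp, Slk, Kcnab2, Tug1, Arf3, Ip6k1 and Tspan2, with log2 changes from 1.87 for Tug1 to 2.74 for Hnrnpab and adjusted p from 0.0128 to 0.0171.

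Among decreases, Polr2a, the largest subunit of RNA polymerase II, fell by 2.08 ± 0.20 on the log2 scale (adjusted p = 0.0132), from a signal of 426 ± 50.5 to 88.5 ± 11.6 (SD, n = 3). Rph3a, a vesicle-associated Rab effector, changed by -1.90 ± 0.24, Sncb, which encodes beta-synuclein, by -1.51 ± 0.18, and Nlgn2, the neuroligin of inhibitory synapses, by -1.46 ± 0.19. Cacng4, an auxiliary subunit of AMPA receptors, fell from a signal of 468 ± 56.7 to 106 ± 24 (SD, n = 3), and Mt3, the brain metallothionein, changed by -1.42 ± 0.18. The largest of the 15 decreases with the smallest p were in Them6 (-2.35 ± 0.29) and 1700037H04Rik (-2.29 ± 0.23). The others were in Arid1a, Slc25a39, Pum2, Rnf208, Mapre3, Pcdh19 and Sez6l, between -1.72 for Pum2 and -1.39 for Slc25a39. Adjusted p ranged from 0.0132 to 0.018, and each of the 30 probe sets lay on the same side of all 3 heterozygous arrays on all 3 knockout arrays.

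Most of the raised probe sets were not the brightest of their gene. Of the 229 that had another tested probe set for the same gene, 198 (86.5%) had a brighter one, and the brightest one changed by a median of 0.03 on the log2 scale against 1.60 for the raised ones. The brightest probe set changed by -0.09 ± 0.23 for Norad, 0.27 ± 0.19 for Syt1 and 0.06 ± 0.18 for Map2. It changed by -0.46 ± 0.31 for Kif5c and -0.27 ± 0.19 for Tug1, and none of the 5 passed the threshold. For the 96 lowered probe sets with another one tested, the brightest other changed by a median of -0.26 against -1.21. The 2 probe sets of Vamp2, a vesicle SNARE protein, were called in opposite directions, the brighter at -1.06 ± 0.16 and the dimmer at 1.75 ± 0.35. Among the 30 probe sets above, a second one of the same gene passed in the same direction for Map2 (2.47 ± 0.31), Syt1 (2.07 ± 0.26), Ip6k1 (1.90 ± 0.32), Slk (1.58 ± 0.25), Tspan2 (1.41 ± 0.28) and 1700037H04Rik (-1.32 ± 0.20). For the other genes among the 30 the call holds for 1 probe set.

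In all, 445 of 22518 probe sets changed at an adjusted p of 0.05, 280 of them higher and 165 lower, and 400 changed by at least 1 on the log2 scale. An unadjusted p under 0.05 was reached by 4713, against 1126 by chance, and the groups did not overlap for 6179 (27.4%), against 10% by chance. Spiked controls, which are not mouse transcripts, were also higher on every knockout array than on every heterozygous array (below). An effect of genotype on these counts therefore cannot be told apart from a technical difference between the groups' arrays. With the brightest probe set of each of 11467 genes, 116 genes changed, 28 higher and 88 lower, a fit added after the data were seen. With arrays centred on their medians 581 probe sets changed and only 17.2% of them were higher, against 62.9% with the deposited scaling. This centring moved the median of all probe sets by -0.40 on the log2 scale, and 265 of the 445 calls were kept. The count was 0 without knockout 67 (limma; 3926 at an unadjusted p under 0.05), without knockout 68 (3566), without heterozygous 75 (2846) and without heterozygous 81 (3207). It was 29 without heterozygous 76 and 5220 without knockout Ko1. In fits added after the data were seen it was 615 without knockout 67 and 68 (200 of the calls kept) and 4478 without knockout Ko1 and heterozygous 81.

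The direction of the calls varied with the heterozygous signal by which probe sets were binned. Below a heterozygous mean signal of 50, 148 probe sets were called higher and 0 lower (limma), with a median change of 0.34 over 6135 probe sets. Between 200 and 500 there were 13 higher and 71 lower, with a median of -0.21 over 4231. From 4000 upwards there were 18 higher and 0 lower (limma), with a median of 0.56 over 85. The filter on level used the mean over all arrays, whereas these bins use the heterozygous arrays alone. A probe set dim on heterozygous arrays therefore passed the filter more readily if it was higher on knockout arrays. One that fell from such a level was more likely to be removed. The lowest bin thus cannot show whether dim probe sets as such rose.

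**Figure D2:**
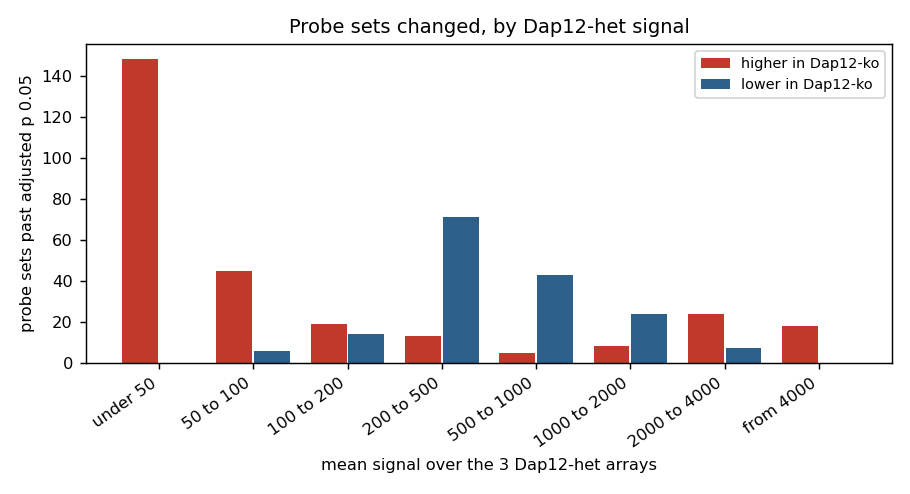
Number of probe sets past an adjusted p of 0.05, higher (red) or lower (blue) on knockout arrays, by mean signal on the 3 heterozygous arrays. Of the increases 148 of 280 lie below a signal of 50. The bin with the most decreases is 200 to 500, with 71 of 165. The filter on level used the mean over all arrays, so probe sets in the lowest bin passed more readily if higher on knockout arrays.

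Microglial genes other than Tyrobp stood slightly higher on the knockout arrays as a group, with no single member past the threshold. Of 31 microglial genes tested, 0 rose and 0 fell (limma), also when adjusted over the list alone, and 22 had changes above 0. The list was shifted by 0.31 on the log2 scale (camera adjusted p = 0.0023; adjusted p = 0.756 with an estimated correlation). C1qa, a complement subunit made by microglia, had signals of 464 ± 117 against 235 ± 9.07 (SD, n = 3; log2 change 0.91 ± 0.22, adjusted p = 0.0748), and the fructose transporter Slc2a5 changed by 1.01 ± 0.31 (adjusted p = 0.12). Csf1r, the receptor that microglia need to survive, was at 1208 ± 116 against 955 ± 187 (0.35 ± 0.19, adjusted p = 0.337). Its 2 other tested probe sets changed by -0.36 ± 0.41 and 0.07 ± 0.24. Cx3cr1, the fractalkine receptor, changed by 0.38 ± 0.23 (adjusted p = 0.383), and Itgam (CD11b) by 0.78 ± 0.37 (adjusted p = 0.265). A second Cx3cr1 probe set was too dim to be tested. It read 42.21, 53.59 and 49.53 on knockout 67, 68 and Ko1 and 7.102, 9.657 and 4.732 on heterozygous 75, 76 and 81. Aif1, which encodes Iba1, changed by -0.18 ± 0.29 (adjusted p = 0.759), and by 0.05 without knockout 67. With arrays centred on their medians the brightest probe sets of Csf1r and Cx3cr1 took the other sign (-0.05 and -0.02). Without knockout Ko1 the shift was 0.17 and the list's call was lost (adjusted p = 0.157), and without a filter on level it was 0.19 (adjusted p = 0.0696).

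Genes of the receptors and enzymes around Tyrobp were shifted by 0.50, with 0 of 14 tested members past the threshold (limma), also when adjusted over the list alone (camera adjusted p = 0.0023; adjusted p = 0.54 with an estimated correlation). Inpp5d, the phosphatase SHIP1, changed by 0.77 ± 0.26 (adjusted p = 0.142) and Pik3cd, a PI3-kinase subunit, by 0.61 ± 0.27 (adjusted p = 0.241). Trem2, Hcst and Syk were too dim to be tested, with mean signals of 17.8, 33.1 and 34.1 on knockout arrays and 9.44, 17.7 and 13.1 on heterozygous arrays. The call was lost with quantile normalization (0.28, adjusted p = 0.0588), with the mean of all probe sets of a gene (0.35, adjusted p = 0.0956) and, among the added fits, without knockout 67 and 68 (0.24, adjusted p = 0.0664).

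Interferon response genes were shifted by 0.50, with 11 of 12 changes above 0 and 0 members past the threshold (limma), also when adjusted over the list alone (camera adjusted p = 0.00149; adjusted p = 0.577 with an estimated correlation). Ifit3 changed by 1.21 ± 0.38 (adjusted p = 0.129) and Irgm1, an interferon-induced GTPase, by 0.57 ± 0.21 (adjusted p = 0.171). This call was lost without a filter on level (0.30, adjusted p = 0.0502) and without knockout 67 and 68 (0.17, adjusted p = 0.184). The complement and antigen presentation list was not shifted (-0.23, camera adjusted p = 0.648). Of 7 genes tested 0 passed over all probe sets (limma) and 1 was lower when adjusted over the list alone. The shift was -0.48 without knockout Ko1 and -0.07 without knockout 67. Its H2-D1, a class I histocompatibility gene, changed by -1.87 ± 0.51 (adjusted p = 0.0925) and Ctss, a lysosomal protease, by 0.33 ± 0.16 (adjusted p = 0.288), the latter taking the other sign with arrays centred on their medians (-0.07). The inflammation and disease-associated microglia list was not shifted (0.38, camera adjusted p = 0.272), with 0 of 9 members past the threshold over all probe sets (limma) and 2 higher and 1 lower when adjusted over the list alone. Its shift was 0.11 without knockout 67. Apoe, the apolipoprotein of glia, changed by 0.52 ± 0.15 (adjusted p = 0.102) and Cst3, cystatin C, by 0.42 ± 0.14 (adjusted p = 0.133), with the other sign for Cst3 under quantile normalization (-0.20).

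Myelin genes were higher on 2 of the 3 knockout arrays. Of 32 genes of myelin and mature oligodendrocytes tested, 3 rose, 1 fell and 28 did not pass. Adjusted over the list alone 5 rose and 1 fell. The list was shifted by 0.58 (camera adjusted p = 7.95e-05; adjusted p = 0.816 with an estimated correlation), by 0.77 on knockout 67, 0.84 on knockout 68 and -0.13 on knockout Ko1. Mbp, myelin basic protein, rose by 1.85 ± 0.35 on the log2 scale, from 6050 ± 341 to 24181 ± 12255 (SD, n = 3; adjusted p = 0.04), and by 0.23 (adjusted p = 0.444) with quantile normalization. Tspan2 rose by 1.41 ± 0.28 (adjusted p = 0.046) and Mal, a lipid raft protein of myelin, by 0.73 ± 0.15 (adjusted p = 0.0478). Myrf, the transcription factor that drives myelin genes, fell by 1.17 ± 0.20 (adjusted p = 0.0354), with the same direction on all 3 knockout arrays. Cnp changed by 0.54 ± 0.19 (adjusted p = 0.155; -0.14 with quantile normalization), Mog by 0.46 ± 0.27 (adjusted p = 0.362) and Mag by -0.05 ± 0.38 (adjusted p = 0.955). Without knockout Ko1 Mag was at 0.45 (adjusted p = 0.0488). The shift was 0.31 without knockout 68, still called, and -0.13 (adjusted p = 0.333) without knockout 67 and 68, an added fit.

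Of the other glial lists, neither was shifted. Of 15 oligodendrocyte precursor genes 1 fell, Cacng4, and 0 rose (limma). Adjusted over the list alone 1 rose and 1 fell, with Lhfpl3 at 0.88 ± 0.23 (adjusted p = 0.0858). The list's shift was -0.04 (camera adjusted p = 0.648). Of 24 astrocyte genes 1 rose, Glul, which encodes glutamine synthetase, by 1.13 ± 0.23 (adjusted p = 0.0485), and it was the only one adjusted over the list alone. Acsbg1 changed by 0.58 ± 0.17 (adjusted p = 0.106), and Gfap, the astrocyte filament protein, was at 462 ± 279 against 1036 ± 437 (-1.25 ± 0.52, adjusted p = 0.219). The 2 other Gfap probe sets tested changed by -1.28 ± 0.45 and 0.62 ± 0.30. The astrocyte list's shift was -0.02, its median -0.11 and its mean -0.05, while camera placed it upwards (adjusted p = 0.648).

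**Figure D3:**
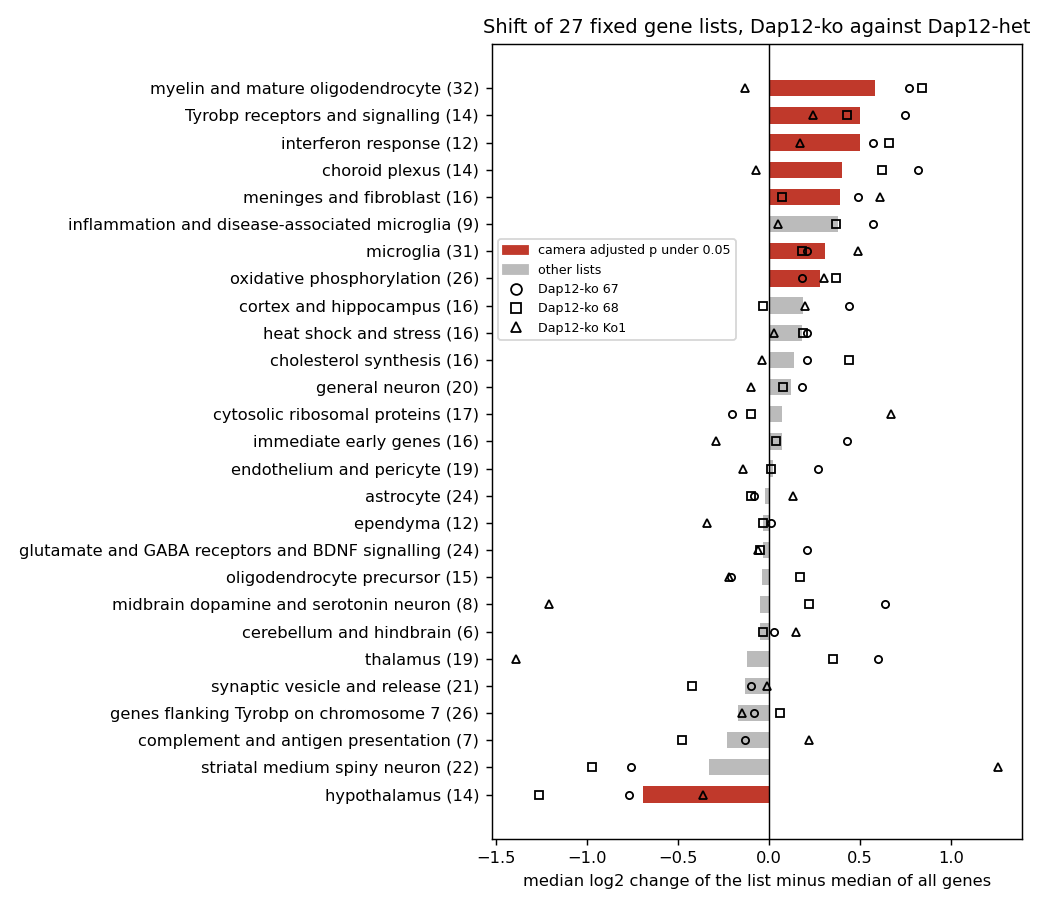
Shift of each gene list (median log2 change of its genes minus the median of all genes; number of genes in brackets), with bars over the 3 knockout arrays together, red where camera's adjusted p was under 0.05, and open symbols for each knockout array against the heterozygous mean. The myelin list lies at 0.77, 0.84 and -0.13 on knockout 67, 68 and Ko1, and the hypothalamus list at -0.77, -1.26 and -0.36.

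Synaptic genes moved both ways. Of 21 genes of synaptic vesicles and release, 2 fell (Sncb and Vamp2, on their brightest probe sets) and 1 rose, Rab3a, a GTPase of vesicle docking, by 1.31 ± 0.23 (adjusted p = 0.0354). Adjusted over the list alone 6 fell and 2 rose, with Syp, synaptophysin, at -1.03 ± 0.21 (adjusted p = 0.0506) and Snap25, a SNARE protein, at 0.88 ± 0.19 (adjusted p = 0.0549). The list was not shifted (-0.13, camera adjusted p = 0.379) but passed among lists without probe sets above a signal of 2000 (-0.16, adjusted p = 0.0135). Of 20 general neuronal genes 0 passed (limma), and adjusted over the list alone 2 were higher and 1 lower. Rbfox3, which encodes NeuN, changed by 0.93 ± 0.21 (adjusted p = 0.0587), while its 2 other tested probe sets went the other way. The list had a median of 0.03, a mean of -0.02 and a shift of 0.12, upwards by camera (adjusted p = 0.671). Of 24 genes of glutamate and GABA receptors and BDNF signalling 0 passed (limma), also when adjusted over the list alone, and the shift was -0.03 (camera adjusted p = 0.985). In that list Dlg4 on its brightest probe set changed by 1.49 ± 0.36 (adjusted p = 0.0735), Ntrk2, the BDNF receptor, by -0.61 ± 0.22 (adjusted p = 0.16) and Bdnf by -0.43 ± 0.43 (adjusted p = 0.603). Bdnf changed by 0.08 without knockout Ko1.

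Hypothalamic genes were lower as a list on all 3 knockout arrays. Of 14 tested, 2 fell and 0 rose, and adjusted over the list alone 5 fell. The list was shifted by -0.69 (camera adjusted p = 0.00296; adjusted p = 0.756 with an estimated correlation), by -0.77, -1.26 and -0.36 on knockout 67, 68 and Ko1. Baiap3 fell by 1.68 ± 0.31 on the log2 scale (826 ± 56.2 to 267 ± 142, SD, n = 3; adjusted p = 0.0391) and Dlk1, an imprinted Notch ligand, by 1.12 ± 0.18 (365 ± 32.8 to 158 ± 2.6; adjusted p = 0.0287). The neuropeptide genes Oxt (oxytocin), Gal (galanin) and Avp (vasopressin) changed by -1.07 ± 0.29, -0.98 ± 0.29 and -0.81 ± 0.64, with adjusted p of 0.0919, 0.113 and 0.503, and Pmch by 0.13 ± 0.68. The list's call was lost with arrays centred on their medians (-0.69, adjusted p = 0.0811), and its shift was -0.36 without knockout 67 and 68. Samples may have held different amounts of hypothalamus, since markers of other regions varied between arrays (below). Such a difference cannot be told apart from an effect of genotype here.

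Markers of other brain regions differed several-fold between arrays of the same genotype. Drd1, the dopamine receptor of the direct striatal pathway, was at 50.7, 53.36 and 804.6 on knockout 67, 68 and Ko1 and at 112.6, 104 and 656.5 on heterozygous 75, 76 and 81. Tcf7l2, a thalamic transcription factor, was at 322, 240.9 and 35.9 against 187.5, 199.2 and 73.72, and Slc6a3, the dopamine transporter of midbrain neurons, at 395.2, 204.9 and 6.451 against 294.8, 252.2 and 12.88. The mean log2 level of striatal genes minus that of thalamic genes was -1.50, -1.29 and 2.19 on the knockout arrays and -0.51, -1.23 and 1.37 on the heterozygous arrays. Knockout Ko1 and heterozygous 81 thus carried more striatal and less thalamic and midbrain signal than the other 4 arrays, and the contrast was wider among the knockouts.

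Between the genotypes, 0 of 22 striatal medium spiny neuron genes, 0 of 19 thalamic genes, 0 of 8 midbrain dopamine and serotonin neuron genes, 0 of 16 genes of cortex and hippocampus and 0 of 6 of cerebellum and hindbrain passed (limma). Adjusted over the list alone only 1 of them did, Nr4a2, a transcription factor of dopamine neurons (-1.12 ± 0.25, adjusted p = 0.0585 over all probe sets). Of its 3 other probe sets tested, 1 fell (-1.57 ± 0.29, adjusted p = 0.0392) and the others were at -0.62 ± 0.32 and 0.37 ± 0.40. Their shifts were -0.33, -0.12, -0.05, 0.19 and -0.05, with camera adjusted p of 0.816, 0.608, 0.68, 0.319 and 0.68. The cerebellum and hindbrain list had a median of -0.14 and a mean of 0.01, upwards by camera. Leaving out 1 array gave calls for the striatal list (-0.93 without knockout Ko1, adjusted p = 0.0368, and 0.37 without heterozygous 81, adjusted p = 0.0416). It also did for the dopamine and serotonin list (-0.76 without heterozygous 81, adjusted p = 0.0315) and the cortex and hippocampus list (0.31 without knockout 68, adjusted p = 0.0431). The cortex and hippocampus list was also called with arrays centred on their medians (0.19, adjusted p = 0.0423), and without knockout 67 and 68 so were the thalamus list (-1.39, adjusted p = 1.08e-06) and, upwards, the striatal list (1.26, adjusted p = 0.00053). Drd1 changed by -0.48 ± 1.00 (0.33 without heterozygous 81 and -1.68 without knockout Ko1) and Drd2 by -0.06 ± 0.43 (0.47 without heterozygous 81). Tcf7l2 changed by 0.07 ± 0.66 (-0.45 without knockout 67 and 0.90 without knockout Ko1) and Th, tyrosine hydroxylase, by -0.21 ± 0.59 (0.30 without knockout Ko1). Adjusted p ran from 0.819 to 0.967. Among the 2 members with the smallest p per list, Isl1 and Rasd2 (striatum) changed by -0.59 and -0.78, Zic4 and Rgs16 (thalamus) by -1.06 and -1.05 and Ddc by -0.44. Only 1 of the 2 other Rgs16 probe sets tested shared its direction, and the other Isl1 probe set tested did not. Dkk3 and Tshz2 (cortex) changed by 1.00 and -0.60, and Hoxa5 and Cbln1 (hindbrain and cerebellum) by 0.61 and -0.52, none past the threshold.

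**Figure D4:**
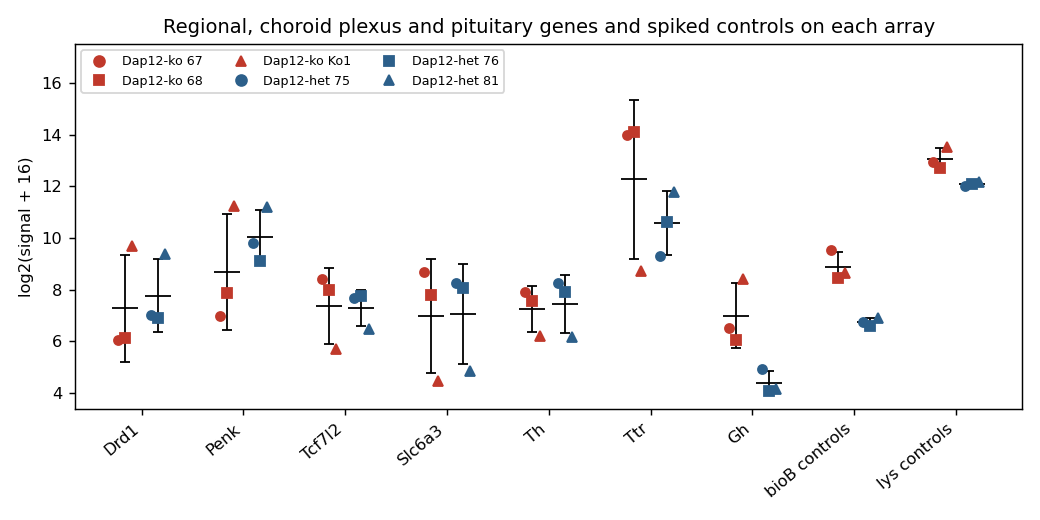
Signals of regional genes, the choroid plexus gene Ttr, the pituitary gene Gh and 2 families of spiked controls on each array, on a log2(signal + 16) axis; red points are knockout arrays, blue points heterozygous arrays, and bars show the mean and SD (n = 3). Drd1 is at 804.6 on knockout Ko1 and 656.5 on heterozygous 81 and below 113 on the other arrays, and both control families are higher on each knockout array.

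Choroid plexus genes were higher on knockout 67 and 68 and not on Ko1. Ttr, transthyretin, the most abundant transcript of this secretory epithelium, was at 16070, 17640 and 401.6 on knockout 67, 68 and Ko1 and at 621.6, 1539 and 3532 on heterozygous 75, 76 and 81 (log2 change 1.69 ± 1.31, adjusted p = 0.496). Kl (Klotho) and Folr1, a folate receptor, changed by 0.98 ± 0.33 and 0.92 ± 0.34, with adjusted p of 0.143 and 0.168. The list was shifted by 0.40 (camera adjusted p = 0.0154; adjusted p = 0.756 with an estimated correlation), by 0.82, 0.62 and -0.07 on the 3 knockout arrays, with 0 of 14 members past the threshold (limma), also when adjusted over the list alone. Its call was lost without knockout 67 (0.28, adjusted p = 0.0836), knockout 68 (0.37, adjusted p = 0.126) or heterozygous 76 (0.24, adjusted p = 0.0551). The shift was 0.68 (adjusted p = 0.00115) without knockout Ko1 and -0.07 without knockout 67 and 68. It was also lost with quantile normalization (0.24, adjusted p = 0.127), with the mean of all probe sets of a gene (0.41, adjusted p = 0.0636) and with the Xist level as a covariate (0.30, adjusted p = 0.0988).

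Meningeal and fibroblast genes were shifted by 0.39 (camera adjusted p = 0.00653; adjusted p = 0.756 with an estimated correlation), with 0 of 16 members past the threshold (limma), also when adjusted over the list alone. Ptgds, a prostaglandin synthase, changed by 0.74 ± 0.20 (adjusted p = 0.0869) and Col1a1, a collagen, by 0.90 ± 0.29 (adjusted p = 0.137), or -0.13 ± 0.47 on its other tested probe set. That call was lost without knockout Ko1 (0.24, adjusted p = 0.157), heterozygous 81 (0.27, adjusted p = 0.169) or both (0.13, adjusted p = 0.517). It was lost with quantile normalization (0.25, adjusted p = 0.142), array weights (0.19, adjusted p = 0.29), no filter on level (0.22, adjusted p = 0.0891), or the mean of all probe sets (0.31, adjusted p = 0.0636). Of 12 ependymal genes 1 fell, Pltp, a phospholipid transfer protein, by 1.23 ± 0.18 (adjusted p = 0.0261), also the only one when adjusted over the list alone. Spag6l changed by 0.69 ± 0.39, and the list was not shifted (-0.03, camera adjusted p = 0.648). Of 19 endothelial and pericyte genes 0 passed (limma), also when adjusted over the list alone. Pdgfrb changed by -0.75 ± 0.24 and Kdr by 0.71 ± 0.40. The list had a median of -0.07, a mean of -0.02 and a shift of 0.02, upwards by camera (adjusted p = 0.848). Gh, growth hormone of the pituitary, was at 75.92, 49.92 and 328.7 on knockout 67, 68 and Ko1 and at 14.62, 1.057 and 1.888 on the heterozygous arrays (2.60 ± 0.58, adjusted p = 0.0592), and was higher when adjusted over the list alone, where it was the only gene tested. Its 3 other probe sets, too dim to be tested, were at 345.5 to 506.5 on knockout Ko1, at 1.67 to 8.993 on knockout 67 and 68, and at 0.3945 to 4.721 on the heterozygous arrays, so only Ko1 stood apart in all 4. Alas2, the only blood cell gene tested, changed by 0.78 ± 0.25 (adjusted p = 0.129), and was higher when adjusted over the list alone.

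Genes of oxidative phosphorylation were shifted by 0.28, with 2 of 26 members higher and 0 lower, and 6 higher when adjusted over the list alone (camera adjusted p = 0.00149; adjusted p = 0.577 with an estimated correlation). Cox6a1, a cytochrome c oxidase subunit, rose by 1.06 ± 0.18 (adjusted p = 0.0351) and Ndufs4, of complex I, by 1.01 ± 0.21 (adjusted p = 0.0496). With quantile normalization they were at 0.21 and 1.09, and neither passed. The list's call was lost with quantile normalization (0.17, adjusted p = 0.163), without a filter on level (0.13, adjusted p = 0.0502), with the mean of all probe sets (0.13, adjusted p = 0.11), without probe sets above a signal of 2000 (0.22, adjusted p = 0.159) and without knockout Ko1 and heterozygous 81 (0.32, adjusted p = 0.0743). The shift was 0.16 without knockout 68, still called.

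Of the remaining lists none was shifted. Of 17 cytosolic ribosomal protein genes 1 rose, Rps29, by 1.09 ± 0.17 (adjusted p = 0.0287), or -0.27 with quantile normalization. Adjusted over the list alone 4 rose, with Rps27 at 1.13 ± 0.29 (adjusted p = 0.0828). That list had a median of -0.02, a mean of 0.08 and a shift of 0.07, upwards by camera (adjusted p = 0.126). It was called without knockout 67 (0.16, adjusted p = 0.00667), without knockout 68 (0.11, adjusted p = 0.0245), without both (0.67, adjusted p = 6.93e-07), with the Xist level as a covariate (0.15, adjusted p = 0.0127) and with arrays centred on their medians (0.07, adjusted p = 0.0244). It turned to -0.15 (adjusted p = 0.993) with quantile normalization. Of 16 heat shock and stress genes 1 rose, Hspa8, a constitutive chaperone, by 1.01 ± 0.20 (adjusted p = 0.0464), or -0.15 with quantile normalization. Adjusted over that list alone 2 rose and 3 fell, with Hspb1 at -1.03 ± 0.22 (adjusted p = 0.0571). Its median was 0.09, its mean -0.04 and its shift 0.18, upwards by camera (adjusted p = 0.615). Of 16 cholesterol synthesis genes 1 rose, Sc5d, a sterol desaturase, by 1.68 ± 0.23 (adjusted p = 0.0205). Adjusted over that list alone 1 rose and 1 fell, with Srebf2, the transcription factor of the pathway, at -1.22 ± 0.25 (adjusted p = 0.0507). The other Srebf2 probe set tested went the other way. The cholesterol list's shift was 0.14 (camera adjusted p = 0.335), called at 0.26 (adjusted p = 0.0406) when 75% of probe sets were removed by level. Of 16 immediate early genes 0 passed (limma), also when adjusted over the list alone. Fosb changed by -0.89 ± 0.30 and Fos by -0.55 ± 0.35. The list had a median of -0.02, a mean of -0.06 and a shift of 0.07, upwards by camera (adjusted p = 0.875), and was called at 0.67 (adjusted p = 0.0155) without knockout Ko1 and heterozygous 81. Over all lists 8 of 27 were shifted, 7 upwards and 1 downwards, against 0 with an estimated correlation and 0 by fry. In them 17 of 462 members changed, 10 higher and 7 lower. In the same fit, on the brightest probe set of each of 11467 genes, 156 genes changed, 41 higher and 115 lower. The number of members was 0 when any array other than knockout Ko1 was left out and 148 without knockout Ko1.

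Genes near Tyrobp on chromosome 7 were examined because a targeted allele carries the surrounding chromosome of the embryonic stem cell strain. Among probe sets of genes within 10 Mb, 47 of 199 (23.6%) had an unadjusted p under 0.05, against 21.2% of 19692 elsewhere, an odds ratio of 1.15 (95% interval 0.808 to 1.61, Fisher's exact p = 0.433). Garre1 rose by 1.59 ± 0.25 (adjusted p = 0.0287) and Akt2, a kinase of insulin signalling, by 1.62 ± 0.28 (adjusted p = 0.0351), each on a dim probe set (13.6 and 17.6 on heterozygous arrays). For Garre1 the other 2 tested probe sets went the other way. Of the fixed list of 26 flanking genes 0 passed (limma), and adjusted over the list alone 2 were lower, Fxyd7, a regulator of the sodium pump, at -1.10 ± 0.23 (adjusted p = 0.0517) and Rbm42 at -0.91 ± 0.22 (adjusted p = 0.0735). The list was not shifted (-0.17, camera adjusted p = 0.272). The odds ratio was 0.98 without heterozygous 75.

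Control measurements separated the genotypes. The bacterial and phage transcripts spiked in before hybridisation were 4.94-fold (bioB), 5.49-fold (bioC), 5.94-fold (bioD) and 3.7-fold (cre) higher on the knockout arrays, and the poly-A controls added to the RNA were 3.54-fold (dap, a bacterial gene unrelated to Dap12), 1.96-fold (lys), 2.36-fold (phe) and 2.86-fold (thr) higher. Each lay higher on all 3 knockout arrays than on all 3 heterozygous arrays (exact permutation p = 0.1, the smallest possible). With arrays centred on their medians their log2 differences were 0.56 to 2.14, and with quantile normalization 0.11 to 2.41, the smallest for the poly-A controls. The ratio of 3' to 5' signal, a measure of how far labelled fragments extend along a transcript, differed for pyruvate carboxylase, at 1.73 ± 0.27 on the log2 scale on knockout arrays and 3.57 ± 0.08 on heterozygous arrays (SD, n = 3; exact permutation p = 0.1). For beta-actin the log2 ratio of 3' to middle signal was 1.01 ± 0.14 against 0.65 ± 0.11 (exact permutation p = 0.1) and of 3' to 5' signal 1.06 ± 0.22 against 0.86 ± 0.21 (exact permutation p = 0.3). For Gapdh the differences were 0.32 (3' to middle, exact permutation p = 0.5) and -0.33 (3' to 5', exact permutation p = 0.4), and for the transferrin receptor -1.02 (3' to 5', exact permutation p = 0.3). The Y-linked gene Eif2s3y was at 57.76, 30.5 and 101.8 on knockout arrays and at 68.31, 59.16 and 62.47 on heterozygous arrays. Xist, expressed from the inactive X chromosome, was highest on knockout 67 in all 3 of its probe sets, at 38.47, 60.24 and 52.32, and on the other 5 arrays reached at most 2.891, 9.529 and 20.25.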

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

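The spiked controls were not part of the planned comparison and differed between the genotypes by more than most genes. The hybridisation controls, spiked in before hybridisation, were 4.94-fold (bioB), 5.49-fold (bioC), 5.94-fold (bioD) and 3.7-fold (cre) higher on the knockout arrays. The poly-A controls, added to the RNA before labelling, were 3.54-fold (dap), 1.96-fold (lys), 2.36-fold (phe) and 2.86-fold (thr) higher. Trpn, a bacterial control labelled as absent, read 1.102 to 4.922 on knockout arrays and 0.9729 to 1.965 on heterozygous arrays. Its 1.54-fold ratio (exact permutation p = 0.4) was taken without the added constant and compares signals near the floor. With the constant added, its log2 difference was 0.07 with the deposited scaling. It was -0.33 with median centring and -0.04 with quantile normalization. These transcripts come from bacteria or phage and are not products of the mouse genome. With quantile normalization the hybridisation controls were still higher by 0.76 (cre) to 2.41 (bioC) on the log2 scale. The arrays of the 2 genotypes thus differed technically, apart from any difference between the mice. The labels do not say whether the 2 genotypes were processed together, and the step at which the difference arose was not tested.

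The tests in this part were chosen after the raised probe sets had been seen. If labelled fragments differed in length between the genotypes, the 6 ratios of 3' signal would differ in the same direction, but 3 were lower and 3 higher on knockout arrays, 2 of the 6 without overlap, which decides nothing. If the genotype raised the whole transcript, the brightest other probe set would move by a like amount. The upper quartile of the ratio was 0.209, so for most of these genes the brightest other probe set did not move by a like amount. The raised probe sets were picked for their rise and the others were not, though, which lowers this ratio to an unknown degree. The ratio therefore does not settle whether whole transcripts rose. A difference between isoforms remains open, and so does a change that varies with signal level, since the raised probe sets were dim (a median heterozygous signal of 40.4) and the brightest others were not (570). The filter on the mean over all arrays also kept dim probe sets more readily when they rose, which may add to this difference in level. Probe sequence was not used here.

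In this part the test of a ceiling was set before its result was seen, and the tests of myelin genes and of region were chosen after. Non-myelin genes with a heterozygous signal above 4000 changed by a median of 0.46 over 39 genes, with 15.4% below 0. A ceiling on the heterozygous arrays was set to need a median above 0.5 and under 10% below 0, and neither was met. The median was not under the 0.2 that would argue against it either, so that test cannot tell. Outside that test, 26 of the genes tested read above 8000 on a knockout array and 0 on a heterozygous array. Of the 85 probe sets with a heterozygous signal from 4000 upwards, 89.4% were higher on knockout arrays. These values go with a limited upper range on the heterozygous arrays. The rises of bright genes such as Rps29 and Hspa8 cannot be told apart from it. Dimmer myelin genes were not higher on every knockout array, the lowest being -0.20, so a rise with genotype and other differences among these arrays cannot be told apart. With the regional score as a covariate the myelin shift was 0.57 against 0.58, but the mean score was -0.20 in knockouts and -0.12 in heterozygotes, so the covariate had little to remove and region stays open.

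For the choroid plexus list the test on dim genes and its bound were set after the values of these genes had been seen, and the test of level was set before. If choroid plexus tissue came with knockout 67 and 68, the 10 choroid plexus genes too dim to be tested would also be higher there. Over genes of like level their median was 0.35 on knockout 67, 0.61 on 68 and -0.19 on Ko1, with 8, 9 and 2 of the 10 above 0, so such tissue is a candidate explanation. Among random lists of like signal level the list median lay at percentile 95.9, so a raised low end of the signal range on the knockout arrays may also contribute. An effect of genotype on choroid plexus genes was not tested apart from these.

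The 6 arrays can be divided 3 against 3 in 10 ways, too few for a share under 0.05. As many changed probe sets as in the real division (445) were found in 1 division, the real one, and the highest other count was 0 (limma; at most 2474 at an unadjusted p under 0.05). For changed list members it was also 1, with 17 and a highest other count of 0. For shifted lists it was 3, with 8 in the real division and up to 10 in the others, so this number of shifted lists arises from other structure among the arrays too. For genes near Tyrobp it was 2, with an odds ratio of 1.15 and a highest other of 1.5. Every other division mixes the genotypes, so any difference between their arrays, technical ones included, widens the spread within its groups. The contrast of 445 with 0 therefore cannot tell an effect of genotype from a technical difference.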

How the results depend on the processing

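The regional covariate, the omission of 2 arrays together, the fit with 1 probe set per gene and the lists without bright probe sets were chosen after the data were seen. The calls depended on single arrays and on the variance model. Tyrobp stayed lower in each setting that tested it, with adjusted p from 0.00709 with array weights to 0.22 without heterozygous 75. Leave-one-out ranges were 0 to 5220 for changed probe sets, 0 to 148 for list members, -1.94 to -1.38 for Tyrobp and 0.98 to 1.22 for the flanking odds ratio. For genes they were -0.34 to 0.05 (Aif1), -1.68 to 0.33 (Drd1), -0.42 to 0.47 (Drd2), -0.45 to 0.90 (Tcf7l2), -0.35 to 0.45 (Mag), -0.71 to 0.08 (Bdnf) and -0.85 to 0.30 (Th). For list shifts they were -0.13 to 0.02 (oligodendrocyte precursor), -0.10 to 0.04 (astrocyte), -0.16 to 0.07 (glutamate and GABA receptors) and -0.93 to 0.37 (striatal). They were -0.41 to 0.54 (thalamus), -0.76 to 0.43 (midbrain), -0.01 to 0.37 (cortex), -0.15 to 0.14 (ependyma) and -0.08 to 0.19 (cerebellum). They were -0.06 to 0.02 (endothelium), -0.22 to 0.27 (immediate early) and -0.11 to 0.16 (ribosomal). Without a change of sign they were 0.17 to 0.44 (microglia), 0.42 to 0.61 (Tyrobp receptors), -0.26 to -0.12 (flanking genes), 0.31 to 0.79 (myelin), 0.02 to 0.18 (general neuron), -0.32 to -0.04 (synaptic vesicle) and -0.96 to -0.54 (hypothalamus). Likewise they were 0.24 to 0.68 (choroid plexus), 0.24 to 0.53 (meninges), 0.41 to 0.66 (interferon), -0.48 to -0.07 (complement) and 0.11 to 0.48 (inflammation). They were 0.10 to 0.25 (heat shock), 0.04 to 0.25 (cholesterol) and 0.16 to 0.33 (oxidative phosphorylation). With 1 probe set per gene 116 genes changed. Camera with an estimated correlation shifted 0 lists, as did fry (0), and the mean of all probe sets shifted 4. With that mean the shift was 0.11 (astrocyte), -0.02 (general neuron), 0.13 (glutamate and GABA receptors), -0.05 (endothelium), -0.03 (immediate early) and -0.01 (ribosomal). Without probe sets above 2000 the ribosomal shift was -0.06.

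Quantile normalization gave 127 probe sets, 4 lists and 5 members. Cst3 was at -0.20, Hspa8 at -0.15, Rps29 at -0.27 and Cnp at -0.14. List shifts were 0.03 (astrocyte), 0.08 (glutamate and GABA receptors), 0.02 (thalamus) and -0.15 (ribosomal). Median centring gave -0.07 for Ctss, -0.05 for Csf1r, -0.02 for Cx3cr1 and -0.34 for Tcf7l2. A floor of 1 gave -3.02 for Tyrobp, which lies at low signal where the added 16 shrinks changes. Without a filter there were 124 probe sets, 5 lists, 6 members, -1.68 for Tyrobp with its call lost, and a flanking odds ratio of 0.97. Shifts were then -0.03 (general neuron), 0.05 (cerebellum), -0.15 (endothelium), 0.27 (complement), -0.08 (immediate early), -0.01 (cholesterol) and -0.08 (ribosomal). A filter that removed 75% of probe sets shifted 5 lists, with 0.01 (astrocyte), 0.03 (glutamate and GABA receptors) and -0.00 (ribosomal). Without a trend there were 180 probe sets, 5 members and -1.68 for Tyrobp, its call lost.

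Array weights gave 4786 probe sets and 118 members, with Mag at 0.27 and Drd2 at 0.14. Shifts were 0.07 (oligodendrocyte precursor), 0.30 (thalamus) and -0.01 (ribosomal). The Xist level used as a covariate was 52.32 on knockout 67 and at most 20.25 elsewhere, so it mostly set that array apart. The tested probe set of Y-linked Eif2s3y read 30.5 to 101.8 on the 6 arrays. The fit is thus close to leaving out knockout 67, which also gave 0 probe sets (limma), and is not a check of sex. The Xist covariate gave 0 probe sets (limma; 3177 at an unadjusted p under 0.05), 0 members, -1.19 for Tyrobp and a flanking odds ratio of 0.90. Aif1 was at 0.12, Drd2 at 0.03 and Tcf7l2 at -0.39. Shifts were 0.02 (oligodendrocyte precursor), 0.02 (astrocyte), 0.05 (striatal), -0.02 (cortex), -0.05 (endothelium), -0.02 (inflammation) and -0.20 (immediate early). The added regional covariate gave 2164 probe sets and 68 members.

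Without knockout 67 and 68, where the lone knockout array is assumed to vary like the heterozygous ones, there were 32 members, a flanking odds ratio of 0.90 and a Gapdh 3' to middle difference of -0.35. Isl1 was at 0.26, Rasd2 at 0.25, Spag6l at -0.20, Kdr at -0.09, Aif1 at 0.13 and Mog at -0.12. Drd1 was at 1.91, Drd2 at 0.32, Tcf7l2 at -1.60 and Ttr at -1.86. Shifts were -0.13 (myelin), 0.13 (astrocyte), -0.10 (general neuron), 1.26 (striatal) and -0.07 (choroid plexus). They were 0.15 (cerebellum), -0.14 (endothelium), 0.22 (complement), -0.29 (immediate early) and -0.04 (cholesterol). Without knockout Ko1 and heterozygous 81, also added, there were 4478 probe sets, 141 members, a flanking odds ratio of 0.90 and a Gapdh 3' to 5' difference of 0.01. Mag was at 0.37 and Drd2 at 0.28. Shifts were 0.03 (oligodendrocyte precursor), 0.02 (glutamate and GABA receptors), 0.29 (thalamus), 0.06 (ependyma) and -0.08 (ribosomal). Of the gene values, 1404 stayed the same, 131 were stronger, 273 weaker and 40 reversed, and of the list values 483, 13, 43 and 75. Tyrobp and the interferon, Tyrobp receptor, choroid plexus and meninges lists had no value when 75% of probe sets were removed, and dim probe sets none where the filter excludes them. Signals under 16 made up 29.16% to 39.78% of probe sets on knockout arrays and 43.31% to 45.27% on heterozygous arrays, which limits what can be read at low signal. Except where stated, the cause was not tested.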

Other observations

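Against 10000 random lists of like signal level, the median change of myelin genes lay at percentile 100, of microglial genes at 99.7, of Tyrobp receptor genes at 99.6, of interferon genes at 99.2, of meningeal genes at 99 and of hypothalamic genes at 0. Oxidative phosphorylation lay at percentile 76.6, genes flanking Tyrobp at 2.56 and striatal genes at 0.39. The striatal list, not called by camera (adjusted p = 0.816), was shifted by -0.76, -0.97 and 1.26 on knockout 67, 68 and Ko1. These percentiles were computed after the list results were seen. Random lists were drawn gene by gene, without the correlation between members of a list. That correlation was estimated at 0.731 for myelin and 0.84 for striatal genes. The percentiles overstate how unusual a list is where its members move together, and camera with an estimated correlation shifted 0 lists.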
